A study of Mus musculus with 15 samples.

How the data were processed

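RNA was sequenced (HiSeq 2000, a low-input strand-keeping kit, 150 ng of total RNA, per the labels) from bone marrow cells sorted after depletion of cells positive for Cd5, Cd11b, B220, Gr-1 or Ter119. The authors deposited 1 table with 28847 RefSeq transcripts, 26343 with NM and 2504 with XM identifiers, and 16 columns of per-library values. Per the file headers these are reads on mm9, with up to 100 hits kept per read, and Bowtie 0.9.9.1 is named in the submitters' processing notes. The deposited unit is an expected count: 13.75% of the values are not whole numbers (tolerance 1e-06), since a read with several hits is divided among them, and no scaling for depth or length was applied. Totals per library ran from 3487772 to 21462900 in the table.

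Of the transcripts, 26092 were matched to a gene symbol, 25973 in a RefSeq gene table and 119 in GENCODE metadata, both possibly of another build than the one the authors used. Transcripts without a match held 4.8% to 5.6% of each library's counts. The 20453 genes include 3566 with several transcripts. Transcripts of a gene share reads: at 1359 genes with a pair of transcripts and a mean count of at least 50 in the higher one, the median ratio of the lower to the higher was 0.972. Each gene was therefore represented by its transcript with the highest mean count, rounded to a whole number, which gave 2469851 to 15092996 counts per library. A gene without counts in a group is given a floor of 3 counts over the group. Where 1 to 3 counts were seen in the lower group, the ratio of pooled counts is given with its exact binomial 95% interval.

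The 15 libraries with a sample were checked for copies: of 105 pairs 0 had identical counts, and the highest rank correlation was 0.956. Another 1 column of the table matches no sample and was not used. For 1 library the title says LTearly and the column name LTlate, so it was left out of every comparison, and its values stand in the closing section. The other 14 entered 1 fit with a mean per group (wtGMP 4, LTearly 4, LTlate 3, BMTGMP 3): edgeR 4.0.16 under R 4.3.3, TMM scaling, the filterByExpr filter, which kept 14553 genes, and the robust quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, 2-sided. The common biological coefficient of variation was 0.748. The 7 contrasts are the 6 pairs of groups and the unweighted mean of the log2 levels of LTearly, LTlate and BMTGMP against wtGMP. Standard errors are the log2 fold change over the square root of F.

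Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 24 lists within a comparison, and again with an estimated correlation and with fry. The 24 lists hold 517 distinct genes, 512 of them in the table: EMT transcription factors and mesenchymal genes, epithelial genes, migration and adhesion, MLL fusion targets, stem cell genes, late neutrophil genes, primary granule genes, monocyte and macrophage genes, proliferation, ribosome biogenesis and MYC targets, interferon response, MHC class II and antigen presentation, oxidative phosphorylation, glycolysis, p53 targets, immediate early and stress genes, drug transport and detoxification, and markers of B cells, T and NK cells, erythroid cells, megakaryocytes, eosinophils, basophils and mast cells, dendritic cells, and stromal and endothelial cells. Genes were named by rule: per comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, up to 4 members with the smallest p of each list spoken of, and always Kmt2a, Mllt3, Zeb1, Mecom, Erg, Hoxa9 and Meis1. Any other gene is said to be chosen after its values were seen. Groups, contrasts, tests, lists, this rule and the alternatives of the next sentence were chosen before the data were examined.

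These alternatives were DESeq2 1.42.0 (Wald test), median-ratio size factors in edgeR, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, the left-out library counted as LTearly or as LTlate, only the groups compared in the fit, transcripts summed per gene, and each library of the groups compared left out in turn. Keeping transcripts without a gene, and thinning every library at random to the lowest total (2469851 counts), were added after seeing the data.

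Recovery was tested on simulated data with the same group sizes, spread as fitted here and 200 genes made to change. The filter left 13166 to 13258 genes, and a changed gene that it removed counted as not recovered. At a true 2-fold change edgeR recovered 17% (LTearly vs wtGMP), 11% (LTlate vs wtGMP), 16% (BMTGMP vs wtGMP), 8% (LTearly vs LTlate), 20% (LTearly vs BMTGMP), 7% (LTlate vs BMTGMP) and 21% (pooled) of the changed genes. At a true 4-fold change it recovered 51%, 37%, 51%, 46%, 46%, 46% and 47% in the same order. False calls by edgeR numbered 2, 3, 3, 5, 1, 3 and 8, and by DESeq2 21, 24, 39, 33, 28, 32 and 39, with 0 edgeR calls in the wrong direction. The list made to change was called by camera in each comparison, and 0 of 23 unchanged lists were. Each gene was drawn independently of the others, so this does not test lists whose members vary together.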

Results

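RNA was sequenced from sorted bone marrow cells of C57BL/6 mice with an inducible MLL-AF9 gene. This human fusion joins part of the histone methyltransferase MLL (mouse gene Kmt2a) to part of AF9 (mouse gene Mllt3) and drives acute myeloid leukaemia. The 14 libraries compared fall into 4 groups: wtGMP (4 libraries), whose name was read as wild-type granulocyte-macrophage progenitors, LTearly (4), LTlate (3) and BMTGMP (3). The labels describe sorting gates for granulocyte-macrophage progenitors and for long-term haematopoietic stem cells. They neither spell out the other 3 group names nor say which gate each library came from, and those 3 are called the MLL-AF9 groups here. Depth moved with group. Counts on named genes came to 4318068 ± 1984950.0 (SD, n = 4) in wtGMP, 4803912 ± 2658101 (n = 4) in LTearly, 13110498 ± 1802689 (n = 3) in LTlate and 7641483 ± 3078341 (n = 3) in BMTGMP. Levels are CPM (counts scaled to a common library size), given as mean ± SD over these libraries, and changes are log2 fold changes ± standard error (SE). Nothing in the labels says that the replicates of a group are separate animals, so each p-value measures the spread between these samples. Counting intervals and floors cover counting error only. Rank correlations between libraries of a group were 0.948 to 0.956 in LTlate, 0.913 to 0.942 in wtGMP, 0.908 to 0.933 in BMTGMP and 0.860 to 0.903 in LTearly. LTearly replicate 4, and by less replicate 3, lay closer to the LTlate libraries than to the other LTearly ones.

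**Figure D1:**
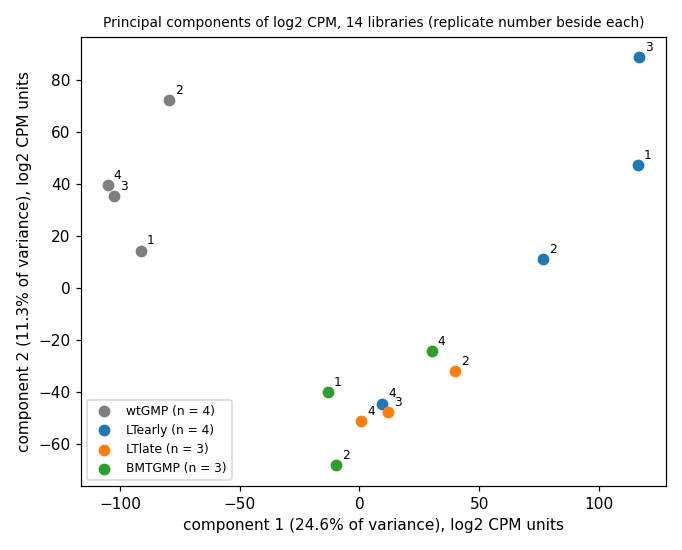
Principal components 1 (24.6% of the variance) and 2 (11.3%) of log2 CPM, with 1 point per library coloured by group. The wtGMP libraries lie between -105 and -79.8 on component 1 and all others between -13.3 and 117, with LTearly replicate 4 at 9.48 beside the LTlate libraries.

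How the MLL-AF9 groups differ on average from wild-type progenitors was tested on the mean of their log2 levels, 10 libraries against 4. A gene or list can pass this test without changing in each group. Late neutrophil genes, which encode granule proteins and receptors of maturing neutrophils, rose. The surface glycoprotein gene Cd177 rose by 6.31 ± 0.48 (adjusted p = 1.76e-06), the granule protein gene Ngp by 7.14 ± 0.61 and the integrin gene Itgb2l by 8.37 ± 0.82. Of 19 late neutrophil genes, 16 rose and 3 were not called (16 rose adjusted over the list alone). Late neutrophil genes were up as a set by camera (adjusted p = 3.43e-19, adjusted p = 0.0385 with an estimated correlation). Both chains of the adhesion receptor Mac-1 rose as well, Itgb2 by 3.36 ± 0.19 (adjusted p = 9.55e-13) and Itgam (CD11b) by 4.03 ± 0.25 (adjusted p = 1.01e-09). Every MLL-AF9 library lay above every wtGMP library at both genes. The gelatinase gene Mmp9 (7.20 ± 0.81) moved with them. Of 35 migration and adhesion genes, 18 rose and 17 were not called (22 rose adjusted over the list alone). Migration and adhesion genes were up as a set by camera (adjusted p = 1.31e-07, adjusted p = 0.0385 with an estimated correlation). In the other direction, the nucleolar gene Npm1 (-1.06 ± 0.13, adjusted p = 1.5e-06), the RNA-modifying enzyme gene Dkc1 (-1.18 ± 0.15) and the mitochondrial chaperone gene Hspd1 (-1.32 ± 0.15) fell. Of 28 ribosome biogenesis and MYC target genes, 24 fell and 4 were not called (26 fell adjusted over the list alone). Ribosome biogenesis and MYC target genes were down as a set by camera (adjusted p = 2.46e-16, adjusted p = 0.0385 with an estimated correlation). The ATP synthase genes Atp5a1 (-0.84 ± 0.12) and Atp5b (-0.71 ± 0.13) fell too. Of 26 oxidative phosphorylation genes, 17 fell and 9 were not called (20 fell adjusted over the list alone). Oxidative phosphorylation genes were down as a set by camera (adjusted p = 2.01e-10, adjusted p = 0.0385 with an estimated correlation).

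Known targets of MLL fusions rose in the pooled comparison, Hoxa9 by 2.72 ± 0.27 (adjusted p = 3.17e-08), Hoxa7 by 2.17 ± 0.22 and Pbx3, a partner of HOX proteins, by 3.69 ± 0.40. Of 27 MLL fusion target genes, 10 rose, 2 fell and 15 were not called (13 rose and 2 fell adjusted over the list alone). MLL fusion target genes were up as a set by camera (adjusted p = 0.000319, adjusted p = 0.15 with an estimated correlation). Meis1, another partner of Hoxa9, rose (2.60 ± 0.39, adjusted p = 0.000308). Its level was 23.9 ± 9.65 CPM in wtGMP, 105 ± 53.5 in LTearly, 121 ± 30.6 in LTlate and 235 ± 48.6 in BMTGMP. Mllt3, the mouse gene of the fusion partner and a stem cell maintenance gene, fell (-2.26 ± 0.44, adjusted p = 0.000425). Kmt2a was not called (0.15 ± 0.16, adjusted p = 0.599). Reads of the human fusion count on these mouse genes only where they match the mouse sequence. Among genes of the epithelial-mesenchymal transition (EMT), the collagen gene Col5a1 (pooled count ratio 121, 95% counting interval 41.2 to 585), the adhesion gene Ncam1 (2.23 ± 0.25, adjusted p = 9.33e-06) and the fibronectin gene Fn1 (4.17 ± 0.71) rose. Of 28 EMT genes, 6 rose, 1 fell and 21 were not called (6 rose and 1 fell adjusted over the list alone). EMT genes were up as a set by camera (adjusted p = 0.0271, adjusted p = 0.238 with an estimated correlation). Zeb1, the EMT transcription factor, fell in this average of logs (-1.67 ± 0.31, adjusted p = 0.000242) although its mean in LTearly lay above wtGMP. That call ended when the library left out of all comparisons was counted as LTlate (adjusted p = 0.265). The stem cell factors Mecom (1.81 ± 1.55, adjusted p = 0.496) and Erg (-0.02 ± 0.24, adjusted p = 0.991) were not called.

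**Figure D2:**
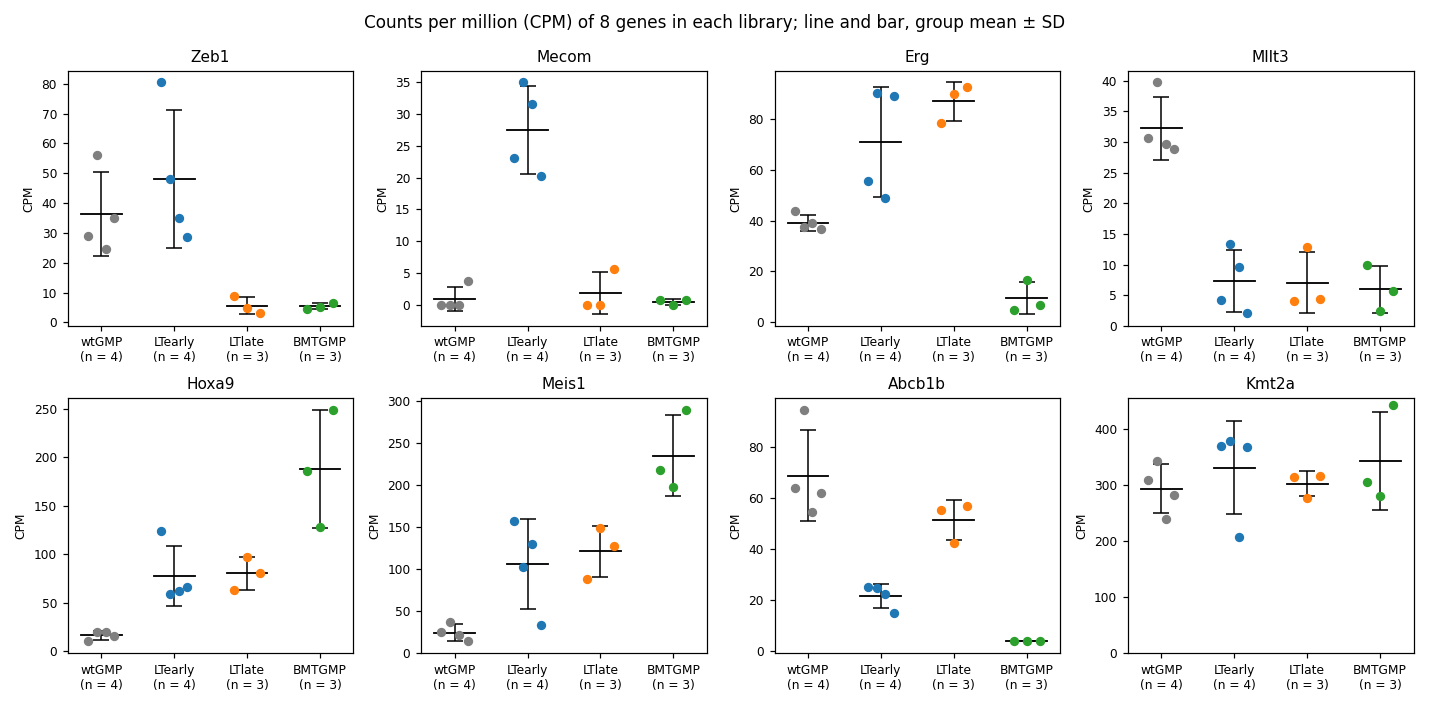
CPM per library (1 point each) of 8 genes in the 4 groups, with lines and bars for mean ± SD. Zeb1 averaged 48 CPM in LTearly, 5.67 in LTlate and 5.41 in BMTGMP.

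Macrophage genes rose in the pooled comparison, led by the oxidase gene Cybb (2.31 ± 0.18, adjusted p = 6.32e-10), the lysozyme gene Lyz2 (2.67 ± 0.19) and Adgre1 (F4/80, 2.60 ± 0.26). Of 25 monocyte and macrophage genes, 10 rose, 1 fell and 14 were not called (11 rose and 1 fell adjusted over the list alone). Monocyte and macrophage genes were up as a set by camera (adjusted p = 0.00182, adjusted p = 0.238 with an estimated correlation). The growth-arrest genes Trp53inp1 (2.51 ± 0.34) and Btg2 (1.41 ± 0.21), targets of p53, rose too. Of 19 p53 target genes, 6 rose and 13 were not called (7 rose adjusted over the list alone). p53 target genes were up as a set by camera (adjusted p = 0.00673, adjusted p = 0.15 with an estimated correlation). The invariant chain gene Cd74 rose (pooled count ratio 95.9, 95% counting interval 26.5 to 793). Of 12 MHC class II and antigen presentation genes, 5 rose and 7 were not called (6 rose adjusted over the list alone). MHC class II and antigen presentation genes were up as a set by camera (adjusted p = 0.0138, adjusted p = 0.238 with an estimated correlation). The junction genes Jup (2.40 ± 0.46, adjusted p = 0.00038) and Cldn1 (at least 40.7-fold higher) rose. Of 12 epithelial genes, 3 rose and 9 were not called (4 rose and 1 fell adjusted over the list alone). Epithelial genes were up as a set by camera (adjusted p = 0.0178, adjusted p = 0.135 with an estimated correlation). The epithelial call was lost without LTearly replicate 4 (adjusted p = 0.0574) and with all libraries thinned to equal depth (adjusted p = 0.0507). The replication helicase genes Mcm7 (-0.79 ± 0.14) and Mcm2 (-0.81 ± 0.15) fell. Of 35 proliferation genes, 1 rose, 8 fell and 26 were not called (1 rose and 9 fell adjusted over the list alone). Proliferation genes were down as a set by camera (adjusted p = 1.03e-05, adjusted p = 0.238 with an estimated correlation). The basophil protease gene Prss34 (adjusted p = 0.00052) and the eosinophil granule gene Prg2 (-3.26 ± 0.50) fell as well in the average of logs. Prss34 had no counts in LTlate (at least 119-fold lower) or BMTGMP (at least 71.7-fold) and averaged 0.62 CPM in LTearly against 9.26 in wtGMP. Prg2 averaged 9.74 ± 7.53 CPM in LTearly and 0.8 ± 0.535 in BMTGMP against 108 ± 49 in wtGMP, but 194 ± 103 in LTlate. Of 11 eosinophil, basophil and mast cell markers, 5 fell and 6 were not called (5 fell adjusted over the list alone). Eosinophil, basophil and mast cell markers were down as a set by camera (adjusted p = 0.000701, adjusted p = 0.0385 with an estimated correlation).

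Lists without a call in the pooled comparison still held genes that moved. Myeloperoxidase (Mpo) fell by 3.25 and haptoglobin (Hp) rose by 1.85 ± 0.17. Of 16 primary granule genes, 5 rose, 5 fell and 6 were not called (6 rose and 7 fell adjusted over the list alone). The list passed in neither direction (camera down, adjusted p = 0.183). Of 20 stem cell genes, 1 rose, 3 fell and 16 were not called (1 rose and 3 fell adjusted over the list alone). Camera called no direction for it (down, adjusted p = 0.757). The median and mean log2 change of stem cell genes (median 0.18 and mean 0.41) had the opposite sign to the test. Of 17 glycolysis genes, 3 rose, 2 fell and 12 were not called (4 rose and 2 fell adjusted over the list alone). By camera the set was not called (up, adjusted p = 0.345). The lactate exporter gene Slc16a3 rose most clearly among them (4.28 ± 0.34, adjusted p = 1.01e-09). Of 20 drug transport and detoxification genes, 5 rose, 2 fell and 13 were not called (6 rose and 3 fell adjusted over the list alone). Neither direction passed for it by camera (up, adjusted p = 0.821). The efflux pump gene Abcb1b fell in this average (-2.08 ± 0.22, adjusted p = 1.2e-07), but LTlate libraries overlapped wtGMP (51.3 ± 8.01 against 68.6 ± 17.7 CPM). The glutathione reductase gene Gsr rose (1.30 ± 0.17). Of 22 immediate early and stress genes, 3 rose and 19 were not called (4 rose and 2 fell adjusted over the list alone). The list passed in neither direction (camera down, adjusted p = 0.821). Their log2 changes (median 0.06 and mean 0.05) were opposite in sign to the test, and Klf2 rose (1.89 ± 0.26). Of 30 interferon response genes, 2 rose, 2 fell and 26 were not called (1 fell adjusted over the list alone). Camera called no direction for it (up, adjusted p = 0.757). Markers of other cell types were tested in the same way. Of 5 megakaryocyte markers, 2 rose and 3 were not called (3 rose adjusted over the list alone). By camera the set was not called (up, adjusted p = 0.101). Of 15 stromal and endothelial markers, 1 rose and 14 were not called (1 rose adjusted over the list alone). Neither direction passed for it by camera (up, adjusted p = 0.166). Of 10 dendritic cell markers, 1 rose and 9 were not called (0 called adjusted over the list alone). The list passed in neither direction (camera up, adjusted p = 0.246). Of 9 erythroid markers, 1 fell and 8 were not called (1 fell adjusted over the list alone). Camera called no direction for it (down, adjusted p = 0.846). The erythroid log2 changes (median 0.57 and mean 1.80) lay against the test's direction. Of 8 B cell markers, edgeR called 0 (0 called adjusted over the list alone), with 1 at an unadjusted p under 0.05 and 0 called by DESeq2. By camera the set was not called (up, adjusted p = 0.747). Of 8 T and NK cell markers, edgeR called 0 (0 called adjusted over the list alone), with 3 at an unadjusted p under 0.05 and 0 called by DESeq2. Neither direction passed for it by camera (up, adjusted p = 0.301).

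**Figure D3:**
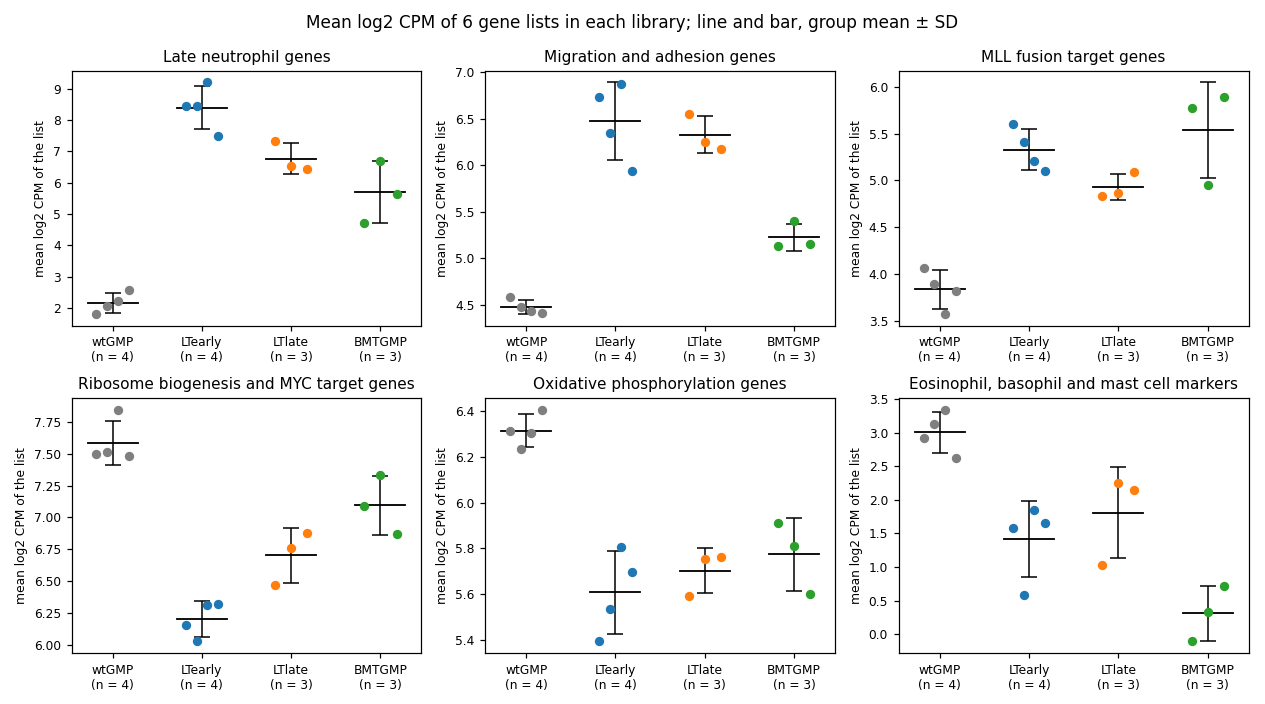
Mean log2 CPM of 6 gene lists in each library (1 point each), by group, with lines and bars for mean ± SD. In the pooled comparison 16 of 19 late neutrophil genes were called higher and 24 of 28 ribosome biogenesis and MYC target genes lower.

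Among the largest pooled changes without overlap, the transglutaminase gene Tgm2 (at least 124-fold higher), the receptor gene Treml4 (at least 74.4-fold) and the adhesion gene Ceacam10 (at least 65.1-fold) had no counts in wtGMP. The floor behind these bounds is 3 counts over the group. The Hedgehog receptor gene Smo fell by 6.46 (adjusted p = 0.00069). Of 14553 genes tested, 2443 changed, 1339 higher and 1104 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Without a low-count filter 1284 were higher and 1291 lower, and 1059 and 731 without wtGMP replicate 3. Some genes named here were not called in each group alone. BMTGMP was not called at Btg2 (adjusted p = 0.0605), Dkc1 (0.216), Fn1 (0.0824), Mcm2 (0.371), Mcm7 (0.301), Mpo (0.321) and Smo (0.0519). LTlate was not called at Abcb1b (0.428) and Prg2 (0.469), nor LTearly at Prss34 (0.128). Of these, DESeq2 called Btg2 (0.0479), Fn1 (0.00525), Smo (0.0388) and Prss34 (0.0479), and Mpo passed with only both groups in the fit (3.87e-05). At 1188 genes the 10 MLL-AF9 libraries did not overlap the 4 wtGMP libraries, against 0.2% of genes by chance.

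How LTearly cells differ from wild-type progenitors was asked next, 4 libraries against 4. Late neutrophil genes rose throughout, Cd177 by 7.40 ± 0.52 (adjusted p = 7.45e-07), Ngp by 8.21 ± 0.66 and Itgb2l by 9.56 ± 0.85. Among 19 late neutrophil genes, 19 rose (19 rose adjusted over the list alone). Camera placed late neutrophil genes up (adjusted p = 1.08e-20, adjusted p = 0.0435 with an estimated correlation). Itgam went from 56.8 ± 18.8 to 1327 ± 349 CPM (4.54 ± 0.27, adjusted p = 4.12e-10). Its partner Itgb2 (3.56 ± 0.20) and the urokinase receptor gene Plaur (2.57 ± 0.33) rose with it. Among 35 migration and adhesion genes, 20 rose and 15 were not called (24 rose and 1 fell adjusted over the list alone). Camera placed migration and adhesion genes up (adjusted p = 2.2e-08, adjusted p = 0.0435 with an estimated correlation). Dkc1 fell by 1.92, Npm1 by 1.65 and the nucleolar gene Nolc1 by 1.54. Among 28 ribosome biogenesis and MYC target genes, 25 fell and 3 were not called (27 fell adjusted over the list alone). Camera placed ribosome biogenesis and MYC target genes down (adjusted p = 1.26e-18, adjusted p = 0.0435 with an estimated correlation). The helicase genes Mcm2 (-1.26 ± 0.19) and Mcm3 (-1.13 ± 0.17) fell. Among 35 proliferation genes, 13 fell and 22 were not called (19 fell adjusted over the list alone). Camera placed proliferation genes down (adjusted p = 7.73e-09, adjusted p = 0.166 with an estimated correlation). The succinate dehydrogenase gene Sdha fell too (-1.10 ± 0.17). Among 26 oxidative phosphorylation genes, 15 fell and 11 were not called (16 fell adjusted over the list alone). Camera placed oxidative phosphorylation genes down (adjusted p = 9.94e-09, adjusted p = 0.0475 with an estimated correlation).

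Hoxa9 rose in LTearly to 77.5 ± 31.1 CPM from 16.1 ± 4.61 (2.29 ± 0.29, adjusted p = 1.53e-06). Hoxa10 (5.48 ± 0.79), Pbx3 (3.62 ± 0.42) and Meis1 (2.14 ± 0.42, adjusted p = 0.0021) rose as well. Among 27 MLL fusion target genes, 11 rose, 1 fell and 15 were not called (12 rose and 1 fell adjusted over the list alone). Camera placed MLL fusion target genes up (adjusted p = 0.00769, adjusted p = 0.204 with an estimated correlation). Mllt3 fell (-2.17 ± 0.58, adjusted p = 0.00769), and neither Kmt2a (0.18 ± 0.19, adjusted p = 0.578) nor Zeb1 (0.41 ± 0.38, adjusted p = 0.503) was called. Col5a1 (pooled count ratio 103, 95% counting interval 34.9 to 501), Fn1 (4.51 ± 0.76) and the TGF-beta receptor gene Tgfbr2 (1.89 ± 0.45, adjusted p = 0.00295) rose. Among 28 EMT genes, 9 rose and 19 were not called (9 rose adjusted over the list alone). Camera placed EMT genes up (adjusted p = 0.00819, adjusted p = 0.169 with an estimated correlation). The desmosome gene Dsp went from 10.9 ± 4.96 to 577 ± 274 CPM (5.70 ± 0.82, adjusted p = 0.000579). Among 12 epithelial genes, 3 rose and 9 were not called (4 rose adjusted over the list alone). Camera placed epithelial genes up (adjusted p = 0.0111, adjusted p = 0.122 with an estimated correlation). Mecom averaged 27.4 ± 6.92 CPM in LTearly against 0.95 ± 1.90 in wtGMP but missed the threshold (4.94 ± 1.80, adjusted p = 0.0745). Every LTearly library lay above every wtGMP library at that gene. Mecom passed when only both groups entered the fit (adjusted p = 0.00579) and without wtGMP replicate 4 (adjusted p = 0.0222), within a range of 0.00495 to 0.157 over its alternatives. It also passed with the left-out library counted as LTearly (adjusted p = 0.0428), with the replicate number as a block (adjusted p = 0.00495) and at equal depth (adjusted p = 0.00521). Erg rose (0.86 ± 0.30, adjusted p = 0.0418). That call was lost without wtGMP replicate 1, 2, 3 or 4 (adjusted p = 0.0654, 0.0871, 0.0869 and 0.0959). It was also lost without LTearly replicate 2 (0.139) or 4 (0.117), with the replicate number as a block (0.0649) and with a filter of 1 CPM in 3 libraries (0.0541). Summing transcripts per gene (0.0637) and keeping transcripts without a gene (0.051) ended it too.

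Macrophage genes rose in LTearly, Cybb by 3.42 ± 0.20 (adjusted p = 2.36e-12) and Lyz2 by 3.42 ± 0.22. Among 25 monocyte and macrophage genes, 13 rose and 12 were not called (14 rose and 1 fell adjusted over the list alone). Camera placed monocyte and macrophage genes up (adjusted p = 6.27e-05, adjusted p = 0.166 with an estimated correlation). Btg2 (2.11 ± 0.24, adjusted p = 3.52e-07) and the stress gene Gadd45a (2.18 ± 0.36) rose. Among 19 p53 target genes, 8 rose and 11 were not called (9 rose adjusted over the list alone). Camera placed p53 target genes up (adjusted p = 0.00427, adjusted p = 0.127 with an estimated correlation). Among 12 MHC class II and antigen presentation genes, 6 rose and 6 were not called (6 rose adjusted over the list alone). Camera placed MHC class II and antigen presentation genes up (adjusted p = 0.00819, adjusted p = 0.204 with an estimated correlation). Prg2 fell by 3.42 and the basophil protease gene Mcpt8 by 2.87. Among 11 eosinophil, basophil and mast cell markers, 2 fell and 9 were not called (3 fell adjusted over the list alone). Camera placed eosinophil, basophil and mast cell markers down (adjusted p = 0.0111, adjusted p = 0.122 with an estimated correlation). The call of these markers was lost without LTearly replicate 2 (adjusted p = 0.0536) and with the left-out library counted as LTlate (0.0508). Among the largest changes without overlap, the acute-phase gene Orm1 was at least 113-fold higher, and the Src-family kinase gene Fgr rose (pooled count ratio 814, 95% counting interval 278 to 3950.0). The cyclophilin gene Ppic was lower (pooled count ratio 244, 95% counting interval 67.2 to 2020.0, wtGMP over LTearly). In all, 2924 genes changed (edgeR's quasi-likelihood test), 1623 higher and 1301 lower. At 3173 genes the groups did not overlap, against 2.86% by chance. The median log2 fold change of all genes was 0.22.

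LTlate libraries, 3 against the 4 of wtGMP, put the same question for that group. Cd177 (5.88 ± 0.50, adjusted p = 7.63e-06), Ngp (7.15 ± 0.64) and Mmp9 (7.88 ± 0.85) rose. Of the 19 late neutrophil genes, 15 rose and 4 were not called (16 rose and 1 fell adjusted over the list alone). As a set, late neutrophil genes were up by camera (adjusted p = 3.76e-18, adjusted p = 0.0608 with an estimated correlation). Itgb2 rose by 3.70 ± 0.21 (adjusted p = 1.3e-12) and Itgam by 4.50 ± 0.27. Of the 35 migration and adhesion genes, 16 rose and 19 were not called (25 rose adjusted over the list alone). As a set, migration and adhesion genes were up by camera (adjusted p = 7.52e-11, adjusted p = 0.019 with an estimated correlation). Hspd1 (-1.27 ± 0.21, adjusted p = 0.000147) and Nolc1 (-1.01 ± 0.17) fell. Of the 28 ribosome biogenesis and MYC target genes, 16 fell and 12 were not called (23 fell adjusted over the list alone). As a set, ribosome biogenesis and MYC target genes were down by camera (adjusted p = 2.23e-14, adjusted p = 0.0688 with an estimated correlation). Atp5a1 fell (-0.71 ± 0.17, adjusted p = 0.00399). Of the 26 oxidative phosphorylation genes, 6 fell and 20 were not called (12 fell adjusted over the list alone). As a set, oxidative phosphorylation genes were down by camera (adjusted p = 4.44e-09, adjusted p = 0.0608 with an estimated correlation). Cybb rose by 2.65 ± 0.20 and Lyz2 by 2.90 ± 0.22. Of the 25 monocyte and macrophage genes, 11 rose and 14 were not called (13 rose and 1 fell adjusted over the list alone). As a set, monocyte and macrophage genes were up by camera (adjusted p = 1.51e-05, adjusted p = 0.133 with an estimated correlation). Mcm7 (-0.93 ± 0.20) and the thymidylate synthase gene Tyms (-1.18 ± 0.27) fell. Of the 35 proliferation genes, 3 fell and 32 were not called (1 rose and 6 fell adjusted over the list alone). As a set, proliferation genes were down by camera (adjusted p = 0.000717, adjusted p = 0.346 with an estimated correlation). The proliferation call did not hold with fry (adjusted p = 0.0891).

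Zeb1 stood at 5.67 ± 2.91 CPM in LTlate against 36.2 ± 14 in wtGMP and fell (-2.67 ± 0.45, adjusted p = 0.000155). The call ended when the left-out library was counted as LTlate (-0.86, adjusted p = 0.551). Other EMT genes rose, Fn1 by 5.54 ± 0.81 (adjusted p = 0.00122) and Ncam1 by 2.24 ± 0.29. Of the 28 EMT genes, 5 rose, 1 fell and 22 were not called (6 rose and 1 fell adjusted over the list alone). As a set, EMT genes were up by camera (adjusted p = 0.0215, adjusted p = 0.243 with an estimated correlation). Hoxa7 rose by 2.32 ± 0.26 (adjusted p = 3.31e-07), Hoxa9 by 2.33 ± 0.30 (adjusted p = 3.4e-06) and Meis1 by 2.35 ± 0.44 (adjusted p = 0.0026). Of the 27 MLL fusion target genes, 10 rose, 2 fell and 15 were not called (11 rose and 2 fell adjusted over the list alone). As a set, MLL fusion target genes were up by camera (adjusted p = 0.000631, adjusted p = 0.133 with an estimated correlation). Erg rose (1.15 ± 0.32, adjusted p = 0.0164), a call lost without LTlate replicate 3 (0.0523) or 4 (0.055). Mllt3 fell (-2.19 ± 0.64, adjusted p = 0.0229). Its call was lost without wtGMP replicate 1 (0.0512) or 2 (0.0668) or LTlate replicate 2 (0.144) or 4 (0.117). Neither Kmt2a (0.04 ± 0.20, adjusted p = 0.951) nor Mecom (1.13 ± 1.75, adjusted p = 0.794) was called. Of the 19 p53 target genes, 5 rose, 1 fell and 13 were not called (7 rose and 1 fell adjusted over the list alone). As a set, p53 target genes were up by camera (adjusted p = 0.0135, adjusted p = 0.133 with an estimated correlation). Of the 12 epithelial genes, 3 rose and 9 were not called (3 rose adjusted over the list alone). As a set, epithelial genes were up by camera (adjusted p = 0.0164, adjusted p = 0.119 with an estimated correlation). Of the 12 MHC class II and antigen presentation genes, 5 rose and 7 were not called (5 rose adjusted over the list alone). As a set, MHC class II and antigen presentation genes were up by camera (adjusted p = 0.0179, adjusted p = 0.27 with an estimated correlation).

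Mpo fell from 17487 ± 1384 to 390.1 ± 141 CPM in LTlate (-5.49 ± 0.76, adjusted p = 0.000822). The extracellular matrix gene Ecm1 (at least 221-fold higher) and the GTPase regulator gene Adap2 (at least 84.9-fold higher) were among the largest rises without overlap. Ppic (at least 296-fold lower) was among the largest falls. Among 5 megakaryocyte markers, 1 rose and 4 were not called (3 rose adjusted over the list alone). Camera placed megakaryocyte markers up (adjusted p = 0.0249, adjusted p = 0.119 with an estimated correlation). This call was lost without wtGMP replicate 3 (adjusted p = 0.0531) or LTlate replicate 3 (0.0767), at equal depth (0.233) and with the replicate number as a block (0.0517). Of the 11 eosinophil, basophil and mast cell markers, 1 fell and 10 were not called (1 fell adjusted over the list alone). As a set, eosinophil, basophil and mast cell markers were down by camera (adjusted p = 0.0249, adjusted p = 0.133 with an estimated correlation). Here the call was lost without wtGMP replicate 2 (0.071) or 3 (0.0992) or LTlate replicate 2 (0.116). It was also lost at equal depth (0.0872) and with the left-out library counted as LTearly (0.067) or as LTlate (0.0504). In all, 1567 genes changed by edgeR's quasi-likelihood test, 1092 higher and 475 lower. At 3777 genes the groups did not overlap, against 5.71% by chance. With only both groups in the fit 2480 genes changed (1499 higher, 981 lower). The count was 917 without LTlate replicate 2 (731 higher, 186 lower) and 1138 without LTlate replicate 3 (877 higher, 261 lower). Genes lower numbered 830 by DESeq2, 311 without wtGMP replicate 3 and 308 without LTlate replicate 4 (higher: 1277, 908 and 919).

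BMTGMP libraries, 3 against the same 4, carried the highest group means of Hoxa9 and Meis1. Hoxa9 reached 187 ± 60.8 CPM (3.56 ± 0.31, adjusted p = 8.64e-09) and Meis1 235 ± 48.6 (3.30 ± 0.45, adjusted p = 0.000297). Hoxa7 (2.43 ± 0.26), the demethylase-like gene Jmjd1c (1.57 ± 0.17) and Pbx3 (3.54 ± 0.43) rose with them. Of 27 MLL fusion target genes, 11 rose, 2 fell and 14 were not called (17 rose and 2 fell adjusted over the list alone). MLL fusion target genes were up as a set by camera (adjusted p = 1.71e-05, adjusted p = 0.154 with an estimated correlation). Cd177 rose by 5.65 ± 0.50 (adjusted p = 1.68e-05), Ngp by 6.05 ± 0.61 and the cathelicidin gene Camp by 7.11 ± 0.77. Of 19 late neutrophil genes, 13 rose and 6 were not called (15 rose adjusted over the list alone). Late neutrophil genes were up as a set by camera (adjusted p = 1.81e-15, adjusted p = 0.0944 with an estimated correlation). Prg2 fell by 7.19 (adjusted p = 0.000712). Of 11 eosinophil, basophil and mast cell markers, 4 fell and 7 were not called (6 fell adjusted over the list alone). Eosinophil, basophil and mast cell markers were down as a set by camera (adjusted p = 1.02e-05, adjusted p = 0.0348 with an estimated correlation). Atp5a1 fell (-0.84 ± 0.17, adjusted p = 0.00125). Of 26 oxidative phosphorylation genes, 3 fell and 23 were not called (8 fell adjusted over the list alone). Oxidative phosphorylation genes were down as a set by camera (adjusted p = 2.06e-08, adjusted p = 0.0944 with an estimated correlation). Of 28 ribosome biogenesis and MYC target genes, 3 fell and 25 were not called (10 fell adjusted over the list alone). Ribosome biogenesis and MYC target genes were down as a set by camera (adjusted p = 3.26e-07, adjusted p = 0.236 with an estimated correlation).

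Erg fell in BMTGMP, to 9.44 ± 6.25 CPM from 39.2 ± 3.17 (-2.05 ± 0.35, adjusted p = 0.000221). The efflux pump gene Abcb1b fell from 68.6 ± 17.7 to 3.81 ± 0.0828 CPM (-4.16 ± 0.36, adjusted p = 8.72e-09). Zeb1 fell too (5.41 ± 0.985 CPM, -2.74 ± 0.46, adjusted p = 0.000186), but was not called with the left-out library counted as LTlate (adjusted p = 0.125). Mllt3 fell (-2.42 ± 0.65, adjusted p = 0.0188), a call lost without wtGMP replicate 2 (0.0578) or BMTGMP replicate 2 (0.102) or 4 (0.0762). Kmt2a (0.23 ± 0.20, adjusted p = 0.615) and Mecom (-0.65 ± 1.93, adjusted p = 0.93) were not called. Ncam1 rose (2.34 ± 0.29, adjusted p = 5.92e-05). Of 28 EMT genes, 2 rose, 2 fell and 24 were not called (3 rose and 2 fell adjusted over the list alone). The list passed in neither direction (camera up, adjusted p = 0.363). Itgb2 rose by 2.83 ± 0.20 (adjusted p = 1.61e-10) and Itgam by 3.05 ± 0.26. Of 35 migration and adhesion genes, 6 rose, 1 fell and 28 were not called (10 rose and 1 fell adjusted over the list alone). Migration and adhesion genes were up as a set by camera (adjusted p = 0.0234, adjusted p = 0.289 with an estimated correlation). The adhesion call was lost without BMTGMP replicate 2 (adjusted p = 0.0654). Among 22 immediate early and stress genes, 1 rose and 21 were not called (0 called adjusted over the list alone). Camera placed immediate early and stress genes down (adjusted p = 0.0238, adjusted p = 0.531 with an estimated correlation). The stress call ended without wtGMP replicate 1 (0.068) or BMTGMP replicate 4 (0.429), and with fry (0.333). Among 15 stromal and endothelial markers, 1 rose and 14 were not called (1 rose adjusted over the list alone). Camera placed stromal and endothelial markers up (adjusted p = 0.0467, adjusted p = 0.194 with an estimated correlation). The stromal call was lost without wtGMP replicate 1, 2, 3 or 4 (adjusted p = 0.116, 0.115, 0.142 and 0.0618). It was lost as well without BMTGMP replicate 1, 2 or 4 (0.0513, 0.0775 and 0.153), with a filter of 1 CPM in 3 libraries (0.0531) and with transcripts summed (0.0598). The LIM protein gene Limch1 (at least 174-fold higher) and the citrate transporter gene Slc13a5 (at least 109-fold) were among the largest rises without overlap. In all, 954 genes changed by edgeR's quasi-likelihood test, 640 higher and 314 lower. Genes lower numbered 167 without BMTGMP replicate 4, 521 with only both groups in the fit and 546 by DESeq2 (higher: 544, 694 and 874). At 2796 genes the groups did not overlap, against 5.71% by chance.

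Other lists that moved in the pooled comparison did not pass in BMTGMP against wtGMP. Of 25 monocyte and macrophage genes, 5 rose, 1 fell and 19 were not called (5 rose and 2 fell adjusted over the list alone). Camera called no direction for it (up, adjusted p = 0.998). Monocyte and macrophage genes had a median log2 change of -0.01 there. Of 35 proliferation genes, edgeR called 0 (0 called adjusted over the list alone), with 4 at an unadjusted p under 0.05 and 2 called by DESeq2. By camera the set was not called (down, adjusted p = 0.0853). The proliferation list passed without wtGMP replicate 2 (adjusted p = 0.0161) or BMTGMP replicate 1 (0.0488), and with the left-out library counted as LTearly (0.0435) or LTlate (0.0464). Of 19 p53 target genes, 2 rose and 17 were not called (4 rose adjusted over the list alone). Neither direction passed for it by camera (up, adjusted p = 0.123). Of 12 epithelial genes, 2 rose, 1 fell and 9 were not called (2 rose and 1 fell adjusted over the list alone). The list passed in neither direction (camera up, adjusted p = 0.303). Both the p53 and the epithelial list passed with fry (adjusted p = 0.041 and 0.0303). Of 12 MHC class II and antigen presentation genes, 3 rose and 9 were not called (3 rose adjusted over the list alone). Camera called no direction for it (up, adjusted p = 0.0958).

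LTearly and LTlate, 4 libraries against 3, differed at few genes. Zeb1 was higher in LTearly (48 ± 23.2 against 5.67 ± 2.91 CPM, 3.08 ± 0.46, adjusted p = 0.00448). So was the G-CSF receptor gene Csf3r (1.56 ± 0.24, adjusted p = 0.00448), though not without LTlate replicate 3 (0.0629). Gadd45a was higher too (2.23 ± 0.40, adjusted p = 0.0126), though not without LTlate replicate 3 (0.0769) or 4 (0.113). The galectin gene Lgals1 was lower in LTearly (-1.44 ± 0.23, adjusted p = 0.00578), as was the transcription factor gene Mef2d (-1.16 ± 0.21, adjusted p = 0.0101, and 0.0768 without LTlate replicate 4). Among 19 late neutrophil genes, 1 was higher and 18 were not called (10 higher adjusted over the list alone). Camera placed late neutrophil genes higher (adjusted p = 2.78e-10, adjusted p = 0.372 with an estimated correlation). Among 28 ribosome biogenesis and MYC target genes, edgeR called 0 (11 lower adjusted over the list alone), with 15 at an unadjusted p under 0.05 and 4 called by DESeq2. Camera placed ribosome biogenesis and MYC target genes lower (adjusted p = 4.36e-08, adjusted p = 0.372 with an estimated correlation). Among 35 proliferation genes, edgeR called 0 (5 lower adjusted over the list alone), with 8 at an unadjusted p under 0.05 and 1 called by DESeq2. Camera placed proliferation genes lower (adjusted p = 1.02e-05, adjusted p = 0.452 with an estimated correlation). Among 30 interferon response genes, edgeR called 0 (2 higher adjusted over the list alone), with 10 at an unadjusted p under 0.05 and 2 called by DESeq2. Camera placed interferon response genes higher (adjusted p = 0.000358, adjusted p = 0.452 with an estimated correlation). The interferon call was lost without LTearly replicate 3 (adjusted p = 0.106). None of these 4 calls held with the fry test (adjusted p = 0.0569, 0.0569, 0.186 and 0.213 in the same order). Hoxa9 (-0.05 ± 0.29, adjusted p = 0.975), Meis1 (-0.20 ± 0.42, adjusted p = 0.924) and Erg (-0.29 ± 0.32, adjusted p = 0.824) were not called. Nor were Mecom (3.81 ± 1.83, adjusted p = 0.449), Mllt3 (0.02 ± 0.61, adjusted p = 0.995) and Kmt2a (0.13 ± 0.20, adjusted p = 0.896). In all, 30 genes changed by edgeR's quasi-likelihood test, 17 higher and 13 lower in LTearly, with 1729 at an unadjusted p under 0.05. At 1483 genes the groups did not overlap, against 5.71% by chance. The count was 198 without LTearly replicate 4 (67 higher, 131 lower), 9 without LTlate replicate 3 and 4 without LTlate replicate 4. It was 264 by DESeq2 (183 higher, 81 lower), 141 without a low-count filter (51 higher, 90 lower) and 52 with a filter of 1 CPM in 3 libraries (19 higher, 33 lower), so the balance of directions was not kept. It was 79 with the left-out library counted as LTearly (33 higher, 46 lower) and 0 with it counted as LTlate (edgeR, with 1483 genes at an unadjusted p under 0.05). Zeb1 then lost its call (adjusted p = 0.719), as it did at equal depth (adjusted p = 0.0574).

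LTearly stood apart from BMTGMP, 4 libraries against 3, by the stem cell factor Erg (71 ± 21.8 against 9.44 ± 6.25 CPM, 2.91 ± 0.36, adjusted p = 1.15e-05). Zeb1 was higher in LTearly as well (3.15 ± 0.47, adjusted p = 0.000122), except with the left-out library counted as LTlate (adjusted p = 0.0837). Dsp was higher (577 ± 274 against 6.56 ± 7.99 CPM, 6.58 ± 0.98, adjusted p = 0.00308), as were the cytoskeletal adaptor gene Eps8l1 (at least 124-fold) and Abcb1b (2.49 ± 0.34, adjusted p = 4.9e-05). The lectin gene Mgl2 (-6.20 ± 0.79, adjusted p = 0.000746) and the collagen gene Col5a3 (-4.83 ± 0.88) were lower in LTearly. Among 27 MLL fusion target genes, 1 was higher, 6 were lower and 20 were not called (4 higher and 10 lower adjusted over the list alone). By camera the set was not called (down, adjusted p = 0.165). That list passed without BMTGMP replicate 2 (adjusted p = 0.0317). Hoxa9 was lower in LTearly (-1.27 ± 0.28, adjusted p = 0.00617) and the myeloid factor gene Mef2c higher (2.52 ± 0.36, adjusted p = 0.000747). Meis1 was not called (-1.16 ± 0.42, adjusted p = 0.133) except without LTearly replicate 4 (adjusted p = 0.0486, range 0.0486 to 0.781). Csf3r was higher by 1.33 ± 0.24 (adjusted p = 0.000955). Of the 19 late neutrophil genes, 13 were higher and 6 were not called (18 higher adjusted over the list alone). As a set, late neutrophil genes were higher by camera (adjusted p = 2.08e-15, adjusted p = 0.0757 with an estimated correlation). Cybb was higher by 2.57 ± 0.22 (adjusted p = 6e-08). Among 25 monocyte and macrophage genes, 7 were higher and 18 were not called (14 higher adjusted over the list alone). Camera placed monocyte and macrophage genes higher (adjusted p = 3.48e-10, adjusted p = 0.0757 with an estimated correlation). Plaur (2.30 ± 0.36), the hyaluronan receptor gene Cd44 (1.47 ± 0.26) and Itgam (1.49 ± 0.26) were higher. Among 35 migration and adhesion genes, 14 were higher and 21 were not called (20 higher adjusted over the list alone). Camera placed migration and adhesion genes higher (adjusted p = 4.71e-08, adjusted p = 0.0591 with an estimated correlation).

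Dkc1 (-1.47 ± 0.20) and Nolc1 (-1.23 ± 0.17) were lower in LTearly than in BMTGMP. Of the 28 ribosome biogenesis and MYC target genes, 13 were lower and 15 were not called (19 lower adjusted over the list alone). As a set, ribosome biogenesis and MYC target genes were lower by camera (adjusted p = 1.08e-13, adjusted p = 0.0757 with an estimated correlation). Of the 35 proliferation genes, 8 were lower and 27 were not called (11 lower adjusted over the list alone). As a set, proliferation genes were lower by camera (adjusted p = 8.97e-08, adjusted p = 0.195 with an estimated correlation). Mcm3 was among the lower ones (-1.27 ± 0.18). The RNA-decay gene Zfp36 (1.59 ± 0.27, adjusted p = 0.000588) and the nuclear receptor gene Nr4a1 (2.66 ± 0.51) were higher. Of the 22 immediate early and stress genes, 6 were higher and 16 were not called (8 higher and 1 lower adjusted over the list alone). As a set, immediate early and stress genes were higher by camera (adjusted p = 2.57e-05, adjusted p = 0.195 with an estimated correlation). Among 28 EMT genes, 3 were higher and 25 were not called (4 higher adjusted over the list alone). Camera placed EMT genes higher (adjusted p = 0.0341, adjusted p = 0.229 with an estimated correlation). The EMT call was lost without LTearly replicate 1 (adjusted p = 0.0791) or 3 (0.0579) or BMTGMP replicate 1 (0.0787) or 2 (0.106). Among 19 p53 target genes, 6 were higher and 13 were not called (7 higher and 1 lower adjusted over the list alone). Camera placed p53 target genes higher (adjusted p = 0.0341, adjusted p = 0.195 with an estimated correlation). The p53 call was lost without LTearly replicate 2 (0.0659) or BMTGMP replicate 4 (0.0753). Among 10 dendritic cell markers, 1 was higher and 9 were not called (1 higher adjusted over the list alone). Camera placed dendritic cell markers higher (adjusted p = 0.0187, adjusted p = 0.0757 with an estimated correlation). Without BMTGMP replicate 4 the dendritic call was lost (0.0753). Mecom (5.59 ± 2.07, adjusted p = 0.149), Mllt3 (0.25 ± 0.61, adjusted p = 0.913) and Kmt2a (-0.05 ± 0.20, adjusted p = 0.954) were not called, though Mecom passed with only both groups in the fit (adjusted p = 0.0053, range 0.0053 to 0.356). It also passed with the replicate number as a block (0.0328) and at equal depth (0.0352). In all, 907 genes changed by edgeR's quasi-likelihood test, 497 higher and 410 lower in LTearly. At 2267 genes the groups did not overlap, against 5.71% by chance. The count was 1500 by DESeq2 (966 higher, 534 lower), 407 with only both groups in the fit (267 higher, 140 lower) and 581 without BMTGMP replicate 1 (337 higher, 244 lower). Without BMTGMP replicate 4, 264 were higher and 364 lower, and without LTearly replicate 4, 627 and 643.

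LTlate and BMTGMP, 3 libraries each, differed by Erg (86.9 ± 7.53 against 9.44 ± 6.25 CPM, 3.20 ± 0.37, adjusted p = 7.32e-06). Abcb1b (3.74 ± 0.36, adjusted p = 1.08e-06), the lipoprotein lipase gene Lpl (6.49 ± 0.87, adjusted p = 0.00132) and the laminin receptor gene Itga6 (2.75 ± 0.44, adjusted p = 0.00129) were higher in LTlate. Prg2 was higher as well (194 ± 103 against 0.8 ± 0.535 CPM, 8.03 ± 0.99, adjusted p = 0.00132). The homeobox gene Six4 was lower in LTlate (at least 494-fold). Cybb was higher by 1.79 ± 0.22 (adjusted p = 1.46e-05) and Lyz2 by 1.22 ± 0.23. Of the 25 monocyte and macrophage genes, 4 were higher and 21 were not called (11 higher adjusted over the list alone). As a set, monocyte and macrophage genes were higher by camera (adjusted p = 3.06e-10, adjusted p = 0.0657 with an estimated correlation). Of the 35 migration and adhesion genes, 7 were higher and 28 were not called (13 higher adjusted over the list alone). As a set, migration and adhesion genes were higher by camera (adjusted p = 7.78e-10, adjusted p = 0.0257 with an estimated correlation). Of 19 late neutrophil genes, edgeR called 0 (0 called adjusted over the list alone), with 4 at an unadjusted p under 0.05 and 1 called by DESeq2. Late neutrophil genes were higher as a set by camera (adjusted p = 0.000103, adjusted p = 0.316 with an estimated correlation). Of 28 ribosome biogenesis and MYC target genes, 1 was lower and 27 were not called (3 lower adjusted over the list alone). Ribosome biogenesis and MYC target genes were lower as a set by camera (adjusted p = 8.29e-05, adjusted p = 0.314 with an estimated correlation). Neither of these 2 calls held with fry (adjusted p = 0.157 and 0.0844). Among 20 drug transport and detoxification genes, 2 were higher and 18 were not called (4 higher and 1 lower adjusted over the list alone). Camera placed drug transport and detoxification genes higher (adjusted p = 0.0037, adjusted p = 0.0657 with an estimated correlation). Of the 27 MLL fusion target genes, 2 were higher, 3 were lower and 22 were not called (3 higher and 5 lower adjusted over the list alone). Neither direction passed for it by camera (down, adjusted p = 0.258). Mef2c was higher in LTlate (2.41 ± 0.37, adjusted p = 0.00224). Hoxa9 was lower in LTlate (-1.23 ± 0.31, adjusted p = 0.0292). That call was lost without LTlate replicate 2 (0.213) or 4 (0.0966) or BMTGMP replicate 1 (0.0585) or 4 (0.22). It was also lost with the replicate number as a block (0.0684), the left-out library counted as LTlate (0.0529) or transcripts summed (0.0791). Meis1 (-0.96 ± 0.45, adjusted p = 0.423) passed only with both groups alone in the fit (adjusted p = 0.0337, range 0.0337 to 0.956). Zeb1 (0.07 ± 0.46, adjusted p = 0.995), Mecom (1.77 ± 1.87, adjusted p = 0.86), Mllt3 (0.23 ± 0.64, adjusted p = 0.978) and Kmt2a (-0.18 ± 0.22, adjusted p = 0.892) were not called.

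Further lists passed between LTlate and BMTGMP with calls that 1 library could end. Of 22 immediate early and stress genes, 3 were higher and 19 were not called (4 higher adjusted over the list alone). Immediate early and stress genes were higher as a set by camera (adjusted p = 0.0037, adjusted p = 0.37 with an estimated correlation). Among 17 glycolysis genes, edgeR called 0 (3 higher adjusted over the list alone), with 5 at an unadjusted p under 0.05 and 2 called by DESeq2. Camera placed glycolysis genes higher (adjusted p = 0.00445, adjusted p = 0.236 with an estimated correlation). Both calls ended without BMTGMP replicate 4 (adjusted p = 0.101 and 0.065), and that of the stress genes with fry as well (0.157). Among 11 eosinophil, basophil and mast cell markers, 2 were higher and 9 were not called (4 higher and 1 lower adjusted over the list alone). Camera placed eosinophil, basophil and mast cell markers higher (adjusted p = 0.0217, adjusted p = 0.122 with an estimated correlation). The eosinophil call was lost without LTlate replicate 3 (0.0879) or 4 (0.0603) or BMTGMP replicate 1 (0.0866) or 2 (0.0543), and with the replicate number as a block (0.0597). Of the 10 dendritic cell markers, 1 was higher and 9 were not called (2 higher adjusted over the list alone). As a set, dendritic cell markers were higher by camera (adjusted p = 0.0217, adjusted p = 0.122 with an estimated correlation). The dendritic call was lost without LTlate replicate 3 (0.0694) or BMTGMP replicate 4 (0.065) and at equal depth (0.202). Of the 15 stromal and endothelial markers, edgeR called 0 (0 called adjusted over the list alone), with 2 at an unadjusted p under 0.05 and 1 called by DESeq2. As a set, stromal and endothelial markers were lower by camera (adjusted p = 0.0217, adjusted p = 0.122 with an estimated correlation). Without LTlate replicate 4 (0.0858) or BMTGMP replicate 4 (0.101), or at equal depth (0.0926), the stromal call was lost. Of the 5 megakaryocyte markers, edgeR called 0 (1 higher adjusted over the list alone), with 1 at an unadjusted p under 0.05 and 0 called by DESeq2. As a set, megakaryocyte markers were higher by camera (adjusted p = 0.0354, adjusted p = 0.122 with an estimated correlation). The megakaryocyte call was lost at equal depth (0.266) and without 5 of the 6 libraries, at most 0.339 (BMTGMP replicate 1). Of 35 proliferation genes, edgeR called 0 (0 called adjusted over the list alone), with 7 at an unadjusted p under 0.05 and 1 called by DESeq2. Proliferation genes were lower as a set by camera (adjusted p = 0.0447, adjusted p = 0.618 with an estimated correlation). The proliferation call was lost with fry (0.409), at equal depth (0.06) and without 4 of the 6 libraries, at most 0.339 (BMTGMP replicate 1). In all, 288 genes changed by edgeR's quasi-likelihood test, 221 higher and 67 lower in LTlate. At 2977 genes the groups did not overlap, against 10% by chance. The count was 574 by DESeq2 (381 higher, 193 lower) and 454 with only both groups in the fit (319 higher, 135 lower). It was 154 without LTlate replicate 2 (122 higher, 32 lower) and 165 without BMTGMP replicate 4 (128 higher, 37 lower). Without LTlate replicate 3 or 4, 170 and 178 were higher and 37 and 42 lower.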

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

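Tests of the left-out library, of LTearly replicate 4, of depth by thinning and of a single neutrophil population were chosen after the results were seen. A library far from its group was looked for by the gap to its nearest neighbour over the group's range, against Dixon's 95% limit for 4 libraries: chance flags about 1 in 20 groups, and 5 of 64 groups were past the limit. In wtGMP the mean log2 CPM of ribosome biogenesis and MYC targets was 7.85 in replicate 3 against 7.49 to 7.51 in the others (gap ratio 0.934). B cell markers scored 1.60 in wtGMP replicate 2 against at most -0.64 in the others (gap ratio 0.862). Mecom had counts in wtGMP replicate 4 only (3.79 CPM, gap ratio 1). In LTearly, Kmt2a was low in replicate 3 (207 CPM, gap ratio 0.952) and Hoxa9 high in replicate 1 (124 CPM, gap ratio 0.836).

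The change of Zeb1 against wtGMP differed between LTearly and LTlate by 3.08 (adjusted p = 0.00448) and between LTearly and BMTGMP by 3.15 (adjusted p = 0.000122), by the direct test of each pair. That of Erg differed between LTearly and BMTGMP by 2.91 (adjusted p = 1.15e-05) and between LTlate and BMTGMP by 3.20 (adjusted p = 7.32e-06), LTearly and LTlate being higher. The left-out library, which no comparison used, stood above the highest wtGMP library at 6 of the 7 genes always named: Kmt2a at 389 CPM (wtGMP at most 342), Zeb1 at 64 (56.1), Mecom at 91.6 (3.79), Erg at 108 (43.6), Hoxa9 at 121 (19.6) and Meis1 at 410 (36.5). LTlate libraries reached at most 8.86 CPM at Zeb1 (LTearly 80.3), 5.72 at Mecom (LTearly 34.8) and 96.5 at Hoxa9 (LTearly 123). At Kmt2a, Erg and Meis1 the left-out library exceeded every library of both groups, and at Mllt3 it lay within both.

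The left-out library is titled LTearly and named LTlate in the table. Among the 30 genes called between LTearly and LTlate without it, it lay nearer the LTlate mean at 4 and nearer the LTearly mean at 26. At the 198 genes called when LTearly replicate 4 was left out too, it lay nearer LTlate at 66 and nearer LTearly at 132 (66.7%), between the bounds of 80% set for either side, and chance was not excluded for the 30. Over all genes its rank correlation was 0.926 to 0.928 with LTlate and 0.882 to 0.929 with LTearly libraries. Treated alike at genes called from the other 6 libraries, LTearly replicates 1, 2, 3 and 4 lay nearer LTearly at 84.4%, 90.9%, 66.7% and 34.8%. LTlate replicates 2, 3 and 4 did so at 25%, 11.1% and 25%, of 28, 9 and 4 genes. The shares of the left-out library (86.7% and 66.7%) fell among the LTearly values and above the LTlate ones. By the bounds set, a wrong title and a wrong column name cannot be told apart. Most genes lay on the LTearly side, but the library's number, 1, is taken in LTearly and free in LTlate. No biological explanation was tested.

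LTearly replicate 4 resembled the LTlate libraries (rank correlation 0.930 to 0.939) more than the other LTearly ones (0.866 to 0.903). LTearly replicate 3 did as well, by less (0.867 to 0.882 against 0.86 to 0.866), and replicate 1 nearly so (0.878 to 0.886 against 0.86 to 0.879). With all libraries thinned to 1 depth, replicate 3 (0.856 to 0.869 against 0.858 to 0.86) and replicate 1 (0.863 to 0.869 against 0.858 to 0.874) no longer did. At that depth the lowest correlation of replicate 4 with LTlate was 0.905 and its highest with LTearly 0.894, which argues against depth. At the 198 genes called without it, it lay nearer LTlate at 129 and nearer LTearly at 69. An LTlate library under a wrong label and a cell population between both groups, a biological difference that was not tested, cannot be told apart, since 129 of 198 falls between the bounds of 80% set for either side.

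Late neutrophil genes were higher in the MLL-AF9 groups, with S100a9 at 43.8 ± 23.6 CPM in wtGMP and 8866 ± 3138, 2383 ± 632 and 1354 ± 1130.1 in LTearly, LTlate and BMTGMP, and Ltf at 13.7 ± 6.80, 3469 ± 1259, 938 ± 296 and 619.9 ± 463. With all libraries thinned, the 16 members called higher in the pooled comparison all stayed called, which argues against depth. A single kind of neutrophil mixed in at different shares would keep its genes in 1 ratio within every library. With each library's median over the members taken away, 0 of 14 members differed between LTearly and BMTGMP (adjusted p under 0.05, at least 5 CPM in each library), with a median 95% half-width of 0.79 on the log2 scale. The lowest adjusted p was 0.196, at Cd177 (-0.74 ± 0.24). The test followed an earlier count of members, whose SE held the spread of the shares. The test left out 5 low members and LTlate. A half-width of 0.79 cannot decide on such a mixture. The sort was to remove Gr-1 and Cd11b positive cells, yet Itgam (CD11b) rose in each MLL-AF9 group. Genes turned up together by the MLL-AF9 cells would keep their ratio too, which was not tested.

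Other splits of the same libraries into groups of the same sizes were fitted in the same way. The real split called more genes than any other for LTearly vs wtGMP (2924 genes, against at most 2), LTlate vs wtGMP (1567, at most 232) and BMTGMP vs wtGMP (954, at most 99). The same held for LTearly vs BMTGMP (907, at most 671, in the split that put LTearly replicate 4 with BMTGMP) and the pooled comparison (2443, at most 13). There the real split was 1 among 35 (100 for the pooled one), the smallest share possible, unadjusted over comparisons. Chance is unlikely there only if the replicates are separate animals, which the labels do not say. It cannot be excluded for LTearly vs LTlate, where 2 of 35 splits called 30 or more genes. The other called 157, several times the real count, by placing LTearly replicate 4 with LTlate, which points to a structure of the samples. For LTlate vs BMTGMP the 10 splits are too few for a share under 0.05, with 288 genes in the real split and at most 1 in another.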

How the results depend on the processing

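Keeping transcripts without a gene and thinning every library to the lowest total were chosen after seeing the data, the other alternatives before. Of 209 gene values named in the text, 170 were called. All 170 of them kept their direction under every alternative tried, and 155 kept their call in each. Of 168 list tests 70 were called by camera, of which 52 kept their call under each alternative run for lists (each library left out, the left-out library counted, median-ratio factors, the 1 CPM filter, the block, summed transcripts and thinning), 12 with an estimated correlation and 60 with fry, while 23 uncalled tests passed with fry. No called value changed sign.

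The count of genes changed stayed within 1.5 times its value under all alternatives for LTearly vs wtGMP (2337 to 3182 without 1 library, 2573 to 3615 otherwise), BMTGMP vs wtGMP (711 to 888, and 826 to 1420) and the pooled comparison (1790 to 2664, and 2243 to 3007). For LTlate vs wtGMP it was 1567, 917 to 1334 without 1 library, and 2480 with only the groups compared in the fit. For LTearly vs LTlate it was 30, 4 to 198 without 1 library, 264 with DESeq2, 141 with no low-count filter, 52 with a filter of 1 CPM in 3 libraries, 79 with the left-out library counted as LTearly and 0 with it counted as LTlate (edgeR, 1483 genes at an unadjusted p under 0.05). For LTearly vs BMTGMP it was 907, 581 to 1270 without 1 library, 1500 with DESeq2 and 407 with only the groups compared. For LTlate vs BMTGMP it was 288, 154 to 311 without 1 library, 574 with DESeq2 and 454 with only the groups compared. The cause was not tested. The pooled contrast has no value with only the groups compared, since that is the same fit.

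Replicate numbers did not pair the libraries: of 18 pairs with the same number 1 had a correlation over 0.1 (range -0.161 to 0.114, highest for different numbers 0.144), and 3 of 14 libraries correlated best with their own number. With that number as a block the counts were 2742 (LTearly vs wtGMP), 1481 (LTlate vs wtGMP), 861 (BMTGMP vs wtGMP), 37 (LTearly vs LTlate), 804 (LTearly vs BMTGMP), 301 (LTlate vs BMTGMP) and 2294 (pooled). With equal depth they were 2686, 1477, 876, 32, 808, 295 and 2252 in the same order. Median-ratio size factors moved the median log2 fold change of all genes by at most 0.08. Sample titles also carry codes whose parts recur across and within groups, and the labels do not explain them. The part grD2 stands in LTearly replicate 1 and LTlate replicate 3 (correlation -0.016). The part grLT3 stands in LTearly replicate 3 and LTlate replicate 2 (0.08) and in the left-out library. These codes were not used as a block, so a pairing by them was not tested.

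Depth limits what low genes can show: 3 counts over the group came to 0.175 CPM in wtGMP, 0.157 in LTearly, 0.0778 in LTlate and 0.129 in BMTGMP, and a lower level rests on 1 or 2 counts or none. In simulation 7% to 21% of true 2-fold changes were recovered. Fewer genes changed there than most comparisons called, so rates may differ here.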

Other observations

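The genes of this paragraph were chosen after their values were seen, and no list of them was tested. Cd34, part of the gate for granulocyte-macrophage progenitors, stood at 249 ± 27.6 CPM in wtGMP, 32.6 ± 24 in LTearly, 115 ± 27.8 in LTlate and 4.75 ± 1.73 in BMTGMP (pooled -3.25 ± 0.32, adjusted p = 8.95e-06). Kit, the stem cell factor receptor gene, fell in LTearly (-1.89 ± 0.44, adjusted p = 0.00749) and LTlate (-3.08 ± 0.52, adjusted p = 0.00135) and was not called in BMTGMP (-1.54 ± 0.48, adjusted p = 0.0836). There it passed by DESeq2 (adjusted p = 0.00687) and with only both groups in the fit (adjusted p = 0.000104). Ptprc (CD45) rose in the pooled comparison (1.48 ± 0.15, adjusted p = 6.49e-08), and the granulocyte factor gene Cebpe rose (1.97 ± 0.39, adjusted p = 0.00269) while the progenitor factor gene Sox4 fell (-3.35 ± 0.47, adjusted p = 0.000263). The granulocyte repressor gene Gfi1 reached 265 ± 84.6 CPM in BMTGMP, higher than in LTearly by the direct test (LTearly lower, -1.66 ± 0.32, adjusted p = 0.00348). In LTlate the eosinophil granule gene Prg2 stood at 194 ± 103 CPM, near wtGMP (108 ± 49), while Epx, another granule gene of eosinophils, averaged 7.04 ± 6.12 CPM there against 34 ± 10.00 (not called, adjusted p = 0.317).

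Interferon response genes were uneven within LTearly: their mean log2 CPM was 4.85 in replicate 3, 3.84 in replicate 1, 2.60 in replicate 2 and 2.81 in replicate 4, and 2.21 to 2.82 in wtGMP. In replicate 3 the guanylate-binding protein gene Gbp2 stood at 1074 CPM, against at most 21.8 in the other LTearly libraries. No test between single libraries was run.

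The left-out library held 7927531 counts on named genes. Mllt3 stood there at 12.7 CPM, below every wtGMP library (28.7 to 39.6). The unused column of the table was not analysed here, since no sample carries its name.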
